A study of Homo sapiens with 8 samples.

How the data were processed

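Footprint libraries came from HAP1 cells, wild type or RNF14 knockout, at 0 or 30 min after 4SU and UVA treatment, with 2 biological replicates per group per the series design. Per the labels' protocols, lysates were made with cycloheximide and digested with RNase I, ribosomes were pelleted through sucrose, and footprints were size-selected, ligated to a linker, reverse transcribed, circularised and amplified. The submitters' processing notes name cutadapt, STAR 2.7.10a and the human build hg38. The rule for choosing 1 transcript per gene, the counted region and any removal of ribosomal RNA reads are not given in the sources used here.

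The authors deposited 1 table with RPKM values, reads scaled to transcript length and library total, for 19580 transcripts and 8 libraries, with the length of each transcript. Lengths ran from 39 to 81357 nt, with a median of 2384 nt, and 35.2% were multiples of 3, so they include untranslated regions. The column for knockout at 30 min replicate 1 carries a suffix that no label explains; it was matched by genotype, time and replicate. In every library RPKM times length summed to the same total, and within a tolerance of 0.05 every value above 0 was a whole multiple of 1 step, so reads per transcript and the totals in the report were recovered. No matched RNA abundance was analysed here, so a change in footprints can come from RNA level or from translation. With PCR duplicates not marked, intervals cover counting error only.

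The main test was limma-trend (limma 3.58.1, R 4.3.3: lmFit, contrasts.fit and eBayes with trend) on log2(RPKM + 1), for the 11920 transcripts with a mean RPKM of 1 or more. All 8 libraries entered 1 fit of 4 group means with 4 residual degrees of freedom, without a replicate block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale and are not ratios of reads. Contrasts were recovery in each genotype, genotype at each time, their interaction, and recovery averaged over genotypes. RPKM is no count, so a count model, limma voom on the recovered reads, was kept as an alternative. Shares of reads were compared by exact permutation. Ratios of reads carry exact 95% binomial (Clopper-Pearson) intervals.

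On simulated counts with 200 changed transcripts, the fit of recovery in wild type found 2.5% of those changed 2-fold and 66% of those changed 4-fold, among 11892 and 11901 tested transcripts. For recovery averaged over genotypes it found 30.5% and 85%, among 11938 and 11911. All recovered ones had the right direction. False calls at 2-fold and 4-fold made up 16.7% of 6 and 2.94% of 136 calls in wild type. For the average they made up 0% of 61 and 10.5% of 190. All transcripts were given 1 spread beyond counting error (dispersion 0.00842), estimated from well-read ones. Apart from the set changes, all libraries had 1 mean profile. No outlying library and no shift in composition was simulated, so these rates may not hold for the real libraries. Recovery in the knockout, the genotype comparisons and the interaction were not simulated.

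Alternatives chosen beforehand were pseudocounts of 0.1 and 5, no filter or a mean RPKM of 5, TPM scaling, median centring, quantile normalization, a replicate block, no trend in the prior, fits of only the groups compared, voom, and leaving out each library. A filter of 10 reads, libraries thinned to 323946 reads, removal of the most read transcript, and everything about length were added after seeing the data. The rule for named genes, fixed before the data were examined, took for each comparison the 10 largest changes in each direction past the threshold whose replicates do not overlap. Gene IDs could not be paired with names: the gene table used here held 0 rows with an Ensembl ID, so 0 of 19580 could match. For that reason the 28 gene lists fixed beforehand, the lineage markers among them, and the check of RNF14 footprints were not run, 4 IDs are printed, and other transcripts are given by length. Figures were drawn with matplotlib 3.10.9, and other summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.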

Results

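Ribosome footprints were measured in HAP1 cells, an adherent, near-haploid human cell line derived from a chronic myeloid leukaemia line. Wild-type cells were compared with cells in which RNF14 had been knocked out. RNF14 is an E3 ubiquitin ligase that acts on proteins at stalled ribosomes. All cells had received 5 uM 4-thiouridine (4SU) for 18 h and 6 kJ/m2 of UVA light. 4SU is a uridine analogue that is built into new RNA and forms bonds with bound proteins when excited by UVA. Cells were harvested directly after irradiation (0 min) or after 30 min of recovery. Each of the 4 combinations of genotype and time had 2 biological replicates, 8 libraries in all, and every library came from 4SU-treated, irradiated cells. The comparisons ask how footprints changed during recovery from RNA-protein crosslinking, and whether the loss of RNF14 altered that change.

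The table listed 19580 transcripts, 1 per gene, with a length and an RPKM value in each library. Multiplying RPKM by length gave whole reads for 100% of the values above 0. By this reckoning wild type at 0 min had 890647 and 971695 reads and wild type at 30 min had 717828 and 516410. The RNF14 knockout had 1241975 and 778683 reads at 0 min and 323946 and 459227 at 30 min. The deepest library thus held 3.83 times as many reads as the shallowest. Every library at 30 min held fewer reads than every library at 0 min, so depth and recovery time go together. Between 12441 and 13613 transcripts had at least 1 read in a library. Replicates correlated across 11920 tested transcripts with Pearson's r between 0.90, in the knockout at 30 min, and 0.97, in the knockout at 0 min. Along the first principal component, with 26.8% of the variance, the 4 libraries at 0 min had scores from -32.5 to -14.9 and the 4 libraries at 30 min had scores from 6.98 to 55.5. The shallowest library, knockout at 30 min replicate 1, stood apart on the second component, with 19.9% of the variance, at 42.2 against -25.1 for its replicate. The files pair gene IDs with no gene names, and the gene table used here held no Ensembl IDs. Transcripts are therefore described by length and value, and no footprint level of RNF14 itself is given.

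The first question was how reads were spread over transcripts of different length. Footprints lay more on short transcripts at 30 min than at 0 min in both genotypes. Transcripts of up to 600 nt took 7.32% ± 0.767 (SD, n = 2) of all reads in wild type at 0 min and 13.1% ± 1.10 (SD, n = 2) at 30 min. In the knockout the share was 8.71% ± 0.0878 (SD, n = 2) at 0 min and 12.2% ± 0.00667 (SD, n = 2) at 30 min. All 4 libraries at 30 min lay above all 4 at 0 min. Transcripts over 2000 and up to 4000 nt had a smaller share at 30 min, from 29.9% ± 0.731 to 25.6% ± 0.0604 in wild type and from 29.1% ± 0.209 to 26.7% ± 0.164 in the knockout (SD, n = 2 each). For each of these classes an exact two-sided permutation test of recovery time within genotype gave p = 0.0556, the smallest that its 36 arrangements allow, so this test cannot reach 0.05 here. Within 1 genotype, 2 libraries against 2 allow no exact p below 0.333. The length classes were drawn after the data had been seen.

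**Figure D1:**
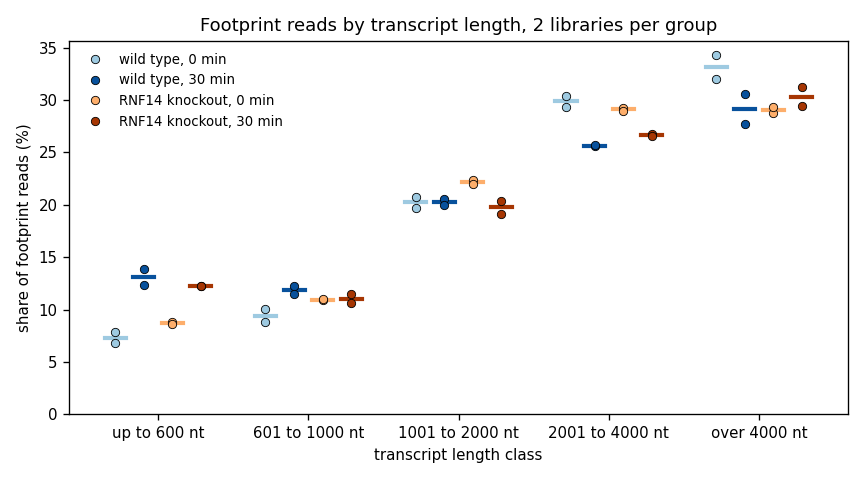
Share of footprint reads (%, vertical axis) on transcripts of 5 length classes (horizontal axis), with 1 point per library and a bar at the mean of the 2 libraries of each group. The class of up to 600 nt has means of 7.32% and 13.1% at 0 and 30 min in wild type and 8.71% and 12.2% in the knockout, while the means of the class over 4000 nt in the knockout differ by 1.26 percentage points, less than its SD of 1.30.

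Reads were also more concentrated at 30 min. The 100 most read transcripts of each library took 19.5% ± 2.10 of reads in wild type at 0 min and 29.1% ± 0.429 at 30 min. In the knockout they took 21.0% ± 0.224 and 28.6% ± 0.136 (SD, n = 2 each). The single most read transcript, of 4298 nt, took 6.77% and 7.22% of reads in the libraries of wild type at 0 min and 7.74% and 9.32% at 30 min. In the knockout libraries it took 5.89% and 6.20% at 0 min and 8.85% and 8.37% at 30 min. The exact permutation test within genotype again gave p = 0.0556 for both measures. Since RPKM is relative to the total, a gain by abundant transcripts lowers the values of all others. The median log2 change of all tested transcripts at 30 min was -0.26 in wild type and -0.12 in the knockout, and directions below are relative to the total unless stated otherwise.

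Recovery in wild type changed 385 of 11920 transcripts at an adjusted p below 0.05 (limma-trend on log2(RPKM + 1), Benjamini-Hochberg), 213 up and 172 down. The risers had a median log2 change of 1.12 and a median length of 1125 nt, against 2625 nt for all tested transcripts. The fallers, with a median length of 1849 nt, were also shorter than the tested transcripts. Of the risers, 43, or 20.2%, were transcripts of up to 600 nt, a class that held 2.79% of the tested transcripts. That percentage of risers was 37.6% without wild type 0 min replicate 2 and 50.7% and 50% without wild type 30 min replicate 1 or 2. It was 13.2% with median centring, 8.80% after quantile normalization and 11.25% with a count model (limma voom). The class also held 19 of the 172 that fell, more than its share of the tested transcripts, so short transcripts were called in both directions. Together the risers took 8.40% ± 0.510 of reads at 0 min and 20.3% ± 1.55 at 30 min (SD, n = 2 each), which restates their selection. Among risers with over 100 reads at 30 min, a transcript of 3137 nt went from 8.89 ± 0.421 to 71.5 ± 6.27 RPKM and a transcript of 3257 nt from 4.62 ± 0.285 to 38.7 ± 0.829 RPKM (SD, n = 2 each). Their log2 changes were 2.87 (SE 0.30, limma adjusted p = 0.000674) and 2.82 (SE 0.31, limma adjusted p = 0.000922). A transcript of 390 nt went from 83.4 ± 20.2 to 492 ± 36.2 RPKM, a log2 change of 2.57 (SE 0.22, limma adjusted p = 0.000201). The largest fitted changes rested on few reads. A transcript of 209 nt, first among the risers by size, had 4 reads at 30 min and is listed at 0 in both libraries at 0 min, and a transcript of 51 nt, first among those that fell, had 3 reads at 0 min and none at 30 min.

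The split into risers and fallers in wild type depended on scaling. It was 213 up and 172 down with RPKM as deposited, 164 and 1271 with TPM, 342 and 22 with each library centred on its median, and 284 and 135 after quantile normalization. The median of all transcripts was -0.52, 0.02 and -0.02 under those 3 alternatives. Under all 4 scalings, 138 transcripts rose and 22 fell. A count model on the recovered reads (limma voom) called 1176 transcripts, 400 up and 776 down. Without a trend in the prior variance 2 were called. Leaving out wild type 30 min replicate 2, wild type 30 min replicate 1 or wild type 0 min replicate 2 left 80, 106 and 117 calls, leaving out knockout 0 min replicate 1 or 2 left 172 and 170, and leaving out knockout 30 min replicate 1 gave 621. Most calls were then down without knockout 30 min replicate 1 (275 up, 346 down) or 2 (247 up, 278 down).

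Recovery in the knockout changed 235 transcripts (limma-trend, adjusted p below 0.05), 77 up and 158 down. Of the risers, 29, or 37.7%, were transcripts of up to 600 nt. That percentage was 58.1% and 57.9% without knockout 0 min replicate 1 or 2, 20.9% after quantile normalization and 18.7% with voom. The class of up to 600 nt also held 27 of the 158 that fell. Risers and fallers had median lengths of 916 and 1061.5 nt, both below the 2625 nt of all tested transcripts. The median log2 change of the class was -0.28, against -0.12 for all tested transcripts. The 390 nt transcript that rose in wild type went from 55.6 ± 14.5 to 347 ± 24.5 RPKM (SD, n = 2 each), a log2 change of 2.64 (SE 0.22, limma adjusted p = 0.000788). A transcript of 1701 nt went from 2.08 ± 0.263 RPKM, on 7 reads, to 41.3 ± 12.2 RPKM, on 57 reads (SD, n = 2 each), a log2 change of 3.75 (SE 0.57, limma adjusted p = 0.0115). A transcript of 1513 nt went from 2.60 ± 0.0809 to 29.8 ± 4.65 RPKM (SD, n = 2 each). Among those that fell, a transcript of 1481 nt had 47 reads at 0 min and 2 at 30 min, and a transcript of 1444 nt had 20 reads at 0 min and is listed at 0 in both libraries at 30 min. The split was 90 up and 491 down with TPM, 44 and 29 with median centring, and 86 and 61 after quantile normalization. Under all 4 scalings 36 transcripts rose and 29 fell. The voom count model called 399, 155 up and 244 down, and the fit without a trend called 0, where 1914 had an unadjusted p below 0.05. Fitted on the knockout libraries alone, 103 were called, 57 up and 46 down, so most calls were then up. There were 22 calls, 19 up and 3 down, without knockout 0 min replicate 2, 45, 31 up and 14 down, without knockout 0 min replicate 1, 120 and 116 without wild type 30 min replicate 1 or 2, and 528 without knockout 30 min replicate 2.

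The 2 recoveries share no library and could be set against each other. Across 11920 transcripts, which are not independent replicates, their log2 changes correlated with Pearson's r = 0.172 and Spearman's rho = 0.130. Of the 213 wild-type risers, 192 had a positive change in the knockout, as had 41.3% of all tested transcripts, and 55 were called there, where independent lists of these sizes would share 1.38. Of the 172 that fell in wild type, 130 had a negative change in the knockout, where 41.3% of all tested transcripts had a positive one. Of these 172, 24 were called in the knockout, against 2.28 for independent lists. Both lists came from 1 fit that shares the variance of each transcript, so a transcript with a low variance is favoured in both. The numbers for independent lists are therefore not the overlap expected by chance. In opposite directions, 2 transcripts were called in both. The agreement depended on single libraries. Pearson's r was 0.0736 and rho 0.0196 without wild type 0 min replicate 2, and 0.0947 and 0.0628 without knockout 30 min replicate 2, while rho was 0.229 without wild type 0 min replicate 1. Without knockout 0 min replicate 1 or 2 Pearson's r was 0.151 and 0.169. Fewer risers were shared there, and the knockout's list of risers was itself shorter. The 24 shared fallers became 5 without wild type 0 min replicate 2, where 9 of 16 wild-type fallers were negative in the knockout, near the share of all transcripts, 4 and 3 without wild type 30 min replicate 1 or 2, and 9 and 2 without knockout 0 min replicate 1 or 2. They became 48 without knockout 30 min replicate 2. Whether the recoveries differed was tested by the interaction of genotype and time, which called 1 of 11920 transcripts (limma-trend, adjusted p below 0.05). That transcript, of 51 nt, had between 0 and 2 reads in every library, and with a filter of at least 10 reads on average 0 transcripts were called. An unadjusted p below 0.05 was reached by 1590 transcripts, more than a fraction of 0.05 of those tested. The interaction has a larger SE than either recovery. On simulated counts the fit of recovery in wild type already found only 2.5% of transcripts changed 2-fold. Few calls thus do not show that the recoveries were alike. The voom count model called 123, 97 higher and 26 lower in the knockout's recovery, and limma-trend called 40 without knockout 30 min replicate 2, 3 without knockout 30 min replicate 1, and 2 without wild type 0 min replicate 2 or wild type 30 min replicate 1.

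**Figure D2:**
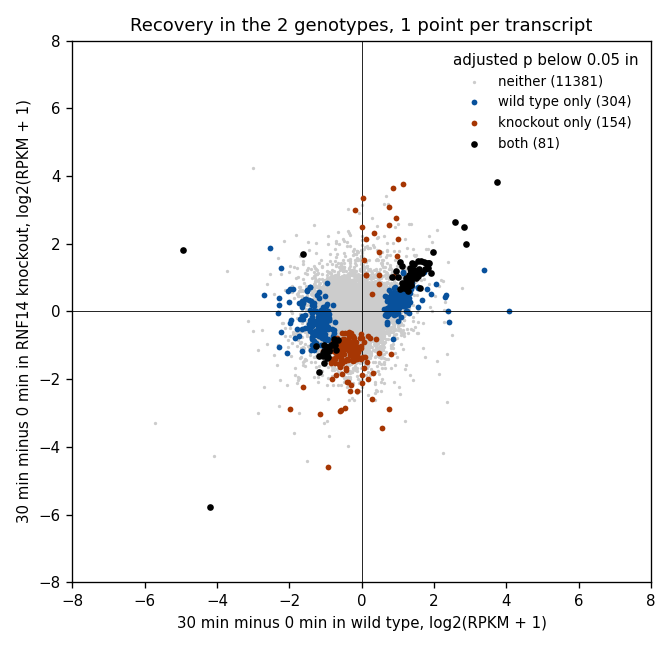
Log2 change from 0 to 30 min of recovery in wild type (horizontal axis) and in the RNF14 knockout (vertical axis), on the log2(RPKM + 1) scale, 1 point per transcript. Points called in both genotypes (81, black) lie mostly in the upper right, where 55 rose in both, and the lower left, where 24 fell in both.

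Averaged over genotypes, 4 libraries against 4, recovery changed 929 transcripts (limma-trend, adjusted p below 0.05), 292 up and 637 down, with a median log2 change of -0.19 over all tested transcripts. Risers and fallers had median lengths of 1397.5 and 1669 nt, both below the 2625 nt of all tested transcripts. The risers took 15.9% ± 0.728 of reads in wild type at 0 min and 29.5% ± 0.441 at 30 min, and 17.8% ± 0.0249 and 29.1% ± 0.0763 in the knockout (SD, n = 2 each). This, too, restates their selection. Among the 333 tested transcripts of up to 600 nt, 45 rose and 56 fell, and their median log2 change of -0.18 was close to that of all transcripts. The 10th riser by size, of 527 nt, went from 1444 ± 25.4 to 5746 ± 996 RPKM in wild type and from 1738 ± 42.1 to 5897 ± 550 RPKM in the knockout (SD, n = 2 each), a log2 change of 1.87 (SE 0.10, limma adjusted p = 6.96e-06). The 3257 nt and 3137 nt transcripts rose by 2.65 (SE 0.22, limma adjusted p = 8.44e-05) and 2.42 (SE 0.21, limma adjusted p = 0.000126) on the log2 scale.

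The first riser by size was ENSG00000124614.16, of 777 nt, with a log2 change of 3.77 (SE 0.41, limma adjusted p = 0.00063). It had 2 reads over the 4 libraries at 0 min and 31 over the 4 at 30 min, a ratio of read shares of 29.8 with an exact 95% counting interval from 7.59 to 257. The first faller was ENSG00000288614.1, of 120 nt, with a log2 change of -4.98 (SE 0.68, limma adjusted p = 0.00245). It had 31 reads at 0 min and 1 at 30 min, a read share 16.1 times lower, with an interval from 2.68 to 656. These intervals cover counting error only. Both calls held under every setting tried in which the transcript was tested. The overall split was 224 up and 1971 down with TPM, 342 and 90 with median centring, and 422 and 247 after quantile normalization, and 202 rose and 90 fell under all 4 scalings. The count was 225 (120 up, 105 down) and 230 (126 up, 104 down) without knockout 0 min replicate 2 or 1, 282 and 392 without wild type 30 min replicate 2 or 1, and 337 without wild type 0 min replicate 2.

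With limma-trend, fewer transcripts were called between the genotypes than in either recovery. This order depends on the test, as voom called 831 for genotype at 0 min against 399 for knockout recovery. Without a trend in the prior, genotype at 0 and 30 min had 3 and 28 calls, against 2 and 0 for recovery in wild type and knockout. At 0 min, directly after irradiation, 20 transcripts differed between knockout and wild type (limma-trend, adjusted p below 0.05), 16 higher and 4 lower in the knockout. The higher ones had a median log2 difference of 2.28. First was ENSG00000185222.10, of 1028 nt, at 0.546 ± 0.772 RPKM in wild type and 134 ± 2.73 RPKM in the knockout (SD, n = 2 each), a log2 difference of 6.55 (SE 0.61, limma adjusted p = 0.00246). It had 1 read in wild type and 280 in the knockout, a ratio of 258 with an exact 95% interval from 45.9 to 10229. With a pseudocount of 0.1 its limma adjusted p was 0.127 and without a trend in the prior 0.0517. A transcript of 6829 nt was at 1.57 ± 0.126 and 62.0 ± 5.22 RPKM, on 20 and 867 reads (SD, n = 2 each), a log2 difference of 4.61 (SE 0.28, limma adjusted p = 0.000107). A transcript of 2591 nt was at 1.23 ± 0.511 and 21.1 ± 1.71 RPKM (SD, n = 2 each).

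The lowest in the knockout was ENSG00000082482.14, of 1491 nt, at 9.73 ± 0.0893 RPKM in wild type and 0.270 ± 0.382 RPKM in the knockout (SD, n = 2 each), a log2 difference of -3.11 (SE 0.39, limma adjusted p = 0.0103). It had 27 reads in wild type and 1 in the knockout, a read share 29.3 times lower, with an exact 95% interval from 4.83 to 1199. Its call was lost in 6 of the 21 other settings, including each fit that left out 1 library at 0 min, with adjusted p up to 0.202 (limma). A transcript of 2150 nt was at 202 ± 4.14 and 24.4 ± 8.56 RPKM (SD, n = 2 each), a log2 difference of -3.04 (SE 0.27, limma adjusted p = 0.00246). The voom count model called 831 transcripts at 0 min, 336 higher and 495 lower, and found all 20 of the limma-trend calls. The count was 64 when only the 4 libraries at 0 min were fitted, and 3 without wild type 0 min replicate 1 or without either knockout library at 0 min. It was 10 without wild type 0 min replicate 2, 13 without either wild-type library at 30 min, and 40 and 34 without knockout 30 min replicate 1 or 2.

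At 30 min, 15 transcripts differed between knockout and wild type (limma-trend, adjusted p below 0.05), 10 higher and 5 lower in the knockout. The 1028 nt transcript was again higher, at 1.88 ± 2.66 RPKM in wild type and 198 ± 30.7 RPKM in the knockout, and the 6829 nt transcript was at 2.54 ± 0.418 and 37.9 ± 2.65 RPKM (SD, n = 2 each). A transcript of 434 nt was at 6.07 ± 4.04 and 123 ± 3.20 RPKM, on 3 and 42 reads (SD, n = 2 each), a log2 difference of 4.26 (SE 0.34, limma adjusted p = 0.000601). The 2150 nt transcript was lower in the knockout, at 110 ± 12.6 and 30.4 ± 8.52 RPKM (SD, n = 2 each). Several of the 15 rested on few reads. The highest by size, of 51 nt, had 0 reads in wild type and 4 in the knockout, and the lowest, of 208 nt, had 7 and 0. With a filter of at least 10 reads on average, 7 of the 15 were kept, and the calls were 14 higher and 1 lower. The comparisons at the 2 times share no library. Across 11920 transcripts, which are not independent replicates, their log2 differences correlated with Pearson's r = 0.0787 and Spearman's rho = -0.0318. Agreement between the times was thus seen for the few called transcripts and hardly across all. Of the 16 higher at 0 min, 14 had a positive difference at 30 min, as had 51.5% of all tested transcripts. At 30 min 6 of them were called, where independent lists would share 0.0134. These lists, too, came from 1 fit with a shared variance, so 0.0134 is not the overlap expected by chance. Of the 4 lower, 2 were called at 30 min. The 6 shared higher transcripts became 3 without wild type 0 min replicate 1 and 2 without either knockout library at 0 min, and the 2 shared lower ones became 0 without any 1 of the wild-type libraries and 1 without either knockout library at 0 min. The voom count model called 21, 20 higher and 1 lower, with 8 of the 15 among them. The limma-trend count was 126, 38 higher and 88 lower, without knockout 30 min replicate 2. It was 26, 10 higher and 16 lower, without knockout 30 min replicate 1, and 8 without wild type 30 min replicate 2.

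**Figure D3:**
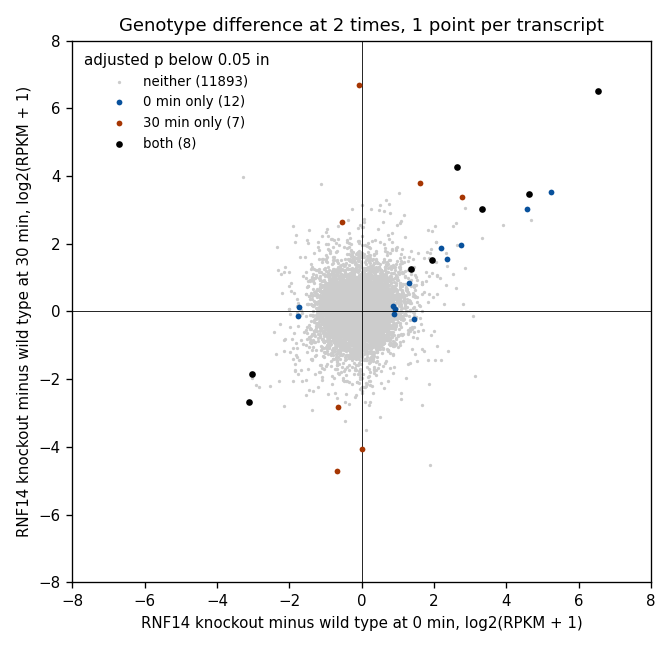
Log2 difference between RNF14 knockout and wild type at 0 min (horizontal axis) and at 30 min (vertical axis), on the log2(RPKM + 1) scale, 1 point per transcript. The 8 transcripts called at both times (black) lie in the upper right, 6, and the lower left, 2, some of them near the edge of the cloud of 11893 called at neither.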

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

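All tests of explanations in this part were chosen after the results had been seen. With 2 libraries per group, no group is large enough to look for single outlying libraries.

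The interaction of genotype and recovery passed the threshold for 1 transcript, of 51 nt, with an interaction of 6.76 on the log2 scale (SE 0.47, limma adjusted p = 0.000463). It had 3 reads in wild type at 0 min and 0 at 30 min, against 3 and 4 in the knockout, 10 in all. Counting error of a handful of reads cannot be told apart from a real difference. An exact conditional test of these reads given their totals gave p = 0.161, but with 10 reads it can give no p below 0.0807, so it could not pass at any threshold used here. The voom count model did not call this transcript. No biological explanation was tested for it.

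The share of reads on transcripts over 4000 nt moved in opposite directions. It went from 33.1% ± 1.63 to 29.2% ± 1.98 in wild type and from 29.0% ± 0.440 to 30.3% ± 1.30 in the knockout (SD, n = 2 each), changes that differ by 5.26 percentage points. The rank correlation of transcript length with the recovery change was -0.106 in wild type and 0.107 in the knockout, and 0.193 with the interaction. It was negative in all 4 pairings of wild-type libraries and positive in all 4 pairings of knockout libraries, though 2 replicates of wild type at 0 min alone gave -0.143. Its size varied between settings. In wild type it was -0.0399 without wild type 0 min replicate 1 and -0.0355 after quantile normalization. In the knockout it was 0.045 without knockout 30 min replicate 1, 0.0534 after quantile normalization and 0.0527 with voom. With the interaction it was 0.0841 after quantile normalization. The rank correlation of length with the genotype difference was -0.186 at 0 min and 0.0868 at 30 min. At 30 min 1 pairing of single libraries gave -0.0244. The share over 4000 nt was 33.1% and 29.0% in wild type and knockout at 0 min, and 29.2% and 30.3% at 30 min. In both measures the genotypes thus differed more directly after irradiation than after recovery.

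For the higher share in the knockout at 30 min, the most read transcript, itself over 4000 nt, is a candidate explanation, since without it the share in the knockout changed by -0.741 points. It does not account for the difference between genotypes, which was still 4.82 points without it. With the exact test used here, which cannot reach 0.05 with these groups, chance differences between libraries cannot be told apart from an effect of genotype. An exact permutation of genotype within each time gave p = 0.111 for the difference, and that test allows none below 0.0556. The same test gave that smallest p for 3 other length classes, whose changes differed by -2.21 points (up to 600 nt), -2.36 points (over 600 and up to 1000 nt) and 1.78 points (over 2000 and up to 4000 nt). The shares add up to the total, so these differences are not independent. An effect of RNF14 loss and a difference in library preparation both stay open and untested.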

How the results depend on the processing

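Counts here are transcripts at an adjusted p below 0.05 (limma), in the order wild-type recovery, knockout recovery, genotype at 0 min, genotype at 30 min, interaction and averaged recovery. With the settings of the report they were 385, 235, 20, 15, 1 and 929. Only values over 1.5 times away are given, and unless a cause is stated it was not tested. With TPM scaling wild-type, knockout and averaged recovery had 1435, 581 and 2195 calls. With median centring knockout and averaged recovery had 73 and 432, and after quantile normalization knockout recovery had 147. Without a trend in the prior the 6 counts were 2, 0, 3, 28, 2 and 99. The voom count model gave 1176 and 399 for the 2 recoveries, 831 for genotype at 0 min and 123 for the interaction. With only the groups compared, knockout recovery had 103, genotype at 0 min 64 and genotype at 30 min 6. Without a filter knockout recovery had 117 and genotype at 0 min 12, and a pseudocount of 0.1 left 10 for genotype at 0 min. Of the settings added after seeing the data, a filter of 10 reads gave 657, 432, 59 and, for the interaction, 0, since it removes the 51 nt transcript. Thinning every library to 323946 reads, and so to less depth, gave 137, 64, 8, 7, 2 and 287. The thinned recoveries had 103 up and 34 down in wild type, 36 and 28 in the knockout, and 140 and 147 averaged. Fallers were thus lost more than risers.

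Leaving out 1 of the 8 libraries at a time leaves 1 group with a lone sample, assumed to vary like the other groups, and gave 80 to 621, 22 to 528, 3 to 40, 8 to 126, 1 to 40 and 225 to 1190 calls. The lowest counts followed the loss of wild type 30 min replicate 2, knockout 0 min replicate 2, several libraries at 0 min, wild type 30 min replicate 2, several libraries and knockout 0 min replicate 2. Knockout 30 min replicate 1 gave the highest count when left out for wild-type recovery and genotype at 0 min, and knockout 30 min replicate 2 for the other 4. In all 8 such fits 64, 21, 2, 6, 1 and 184 of the calls were kept, and 0 changed sign. No shared effect of the replicate numbers was seen, as deviations of same-numbered libraries correlated between -0.08 and 0.07. Whether same-numbered samples were handled together is not shown by this. With the replicate block the counts were 330, 226, 18, 13, 1 and 817.

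The rank correlation of length with averaged recovery, 0.0102, turned to -0.0004 with a mean RPKM of 5, -0.0557 with voom and -0.0112 with thinned libraries, and ranged from -0.0291 to 0.0411 when 1 library was left out. Thinned libraries gave 35.9% and 58.3% of risers of up to 600 nt in wild type and knockout, and no trend in the prior 1 riser in wild type, of that class. Pearson's r of the 2 recoveries was 0.114 with a pseudocount of 0.1 and 0.106 in thinned libraries. Shared risers and fallers of the 2 recoveries, 55 and 24, were 34 and 2 with median centring, 54 and 225 with TPM, 88 and 79 with voom, 32 and 9 in thinned libraries, and 0 and 0 without a trend, while fallers were 14 without a filter, 39 with a mean RPKM of 5 and 65 with 10 reads. The share of reads on transcripts over 4000 nt in the knockout changed by -0.741 points without the most read transcript, in place of 1.26. The share of reads on transcripts of up to 600 nt stayed higher at 30 min in both genotypes without that transcript. Leaving out 1 library could not reverse this direction, since every library at 30 min lay above every library at 0 min. The gene list tests and the RNF14 check, with their alternatives, were not run, as IDs could not be paired with names.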

Other observations

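All tests of explanations in this part were chosen after the results had been seen. Since the files pair IDs with no names, a set-level comparison of lengths was used in place of the gene lists. Genes of 2 lists fixed before the data were examined have no introns, so that a transcript can have the length of its gene: the replication-dependent histones, which package newly made DNA, and the proteins encoded in mitochondria. Lengths of 44 histone genes, 41 of them distinct, were taken from the RefSeq gene table for GRCh38.p14. No single transcript is assigned to a gene by this.

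Of 73 tested transcripts with exactly one of the histone lengths, 31 rose with recovery averaged over genotypes and 5 fell (limma-trend, adjusted p below 0.05). Their median log2 change was 0.68, against -0.19 for all tested transcripts. Together they took 4.05% ± 0.399 of reads in wild type at 0 min and 9.99% ± 0.927 at 30 min, and 5.16% ± 0.144 and 9.55% ± 0.0677 in the knockout (SD, n = 2 each). The median was 0.47 with TPM, 0.86 with median centring and 0.19 after quantile normalization, where all transcripts had medians of -0.37, -0.01 and -0.02. Only 44 genes supplied lengths, so not all of the 73 transcripts can be genes of the list. These medians and read shares therefore mix in other transcripts of the same lengths.

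The gain of transcripts of up to 600 nt may therefore come in large part from histone mRNAs, as a hypothesis. Moving all histone lengths by 1 to 50 nt in either direction gave 100 shifted sets, of 26 to 65 tested transcripts each. The largest share of risers in a shifted set was 31.4% and the largest number 18, against the 42.5%, or 31 of 73, observed. The read share of the whole class rose by 0.66 on the log2 scale, and a size bias that raises every short transcript would need a rise near that. The other 277 transcripts of up to 600 nt had a median log2 change of -0.29 (bootstrap over transcripts, 95% interval -0.38 to -0.18). These are unlike measures, as the share weights transcripts by their reads and the median does not. The interval does not cover variation between libraries. The read share of these 277 went from 3.93% ± 0.411 to 5.01% ± 0.299 in wild type and from 4.48% ± 0.0623 to 4.61% ± 0.226 in the knockout (SD, n = 2 each). On the log2 scale this was 0.35 in wild type and 0.04 in the knockout, on average 0.20. A smaller bias, or one that acts on some of the short transcripts, thus stays open. Nor did 1 transcript carry the gain, as 89.8% of it was left without the transcript that gained most. Of the 20 transcripts with a mitochondrial length 0 rose, against up to 5, or up to 18.5%, in shifted sets. Those shifted sets held 11 to 37 transcripts, so 20 matches are no more than shifted lengths gave. Whether mitochondrial mRNAs are among the 20 is thus not known, and this comparison cannot decide their part in the gain. RNA level and translation cannot be separated in footprints alone, and no effect of the treatment itself was tested, since every library was treated.

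Among the 35 splits of the 8 libraries into 4 and 4, only 1, the split by recovery time, gave as many calls for the averaged recovery. It called 586 transcripts in a simpler model with a term for genotype. The highest of the other splits, that by genotype, called 37 beside a term for time. Of the 35 splits, 17 do not balance the genotypes. The 18 splits with 2 libraries of each genotype on either side, of which the highest other called 1, are too few for a share under 0.05.

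Some transcripts were nearly silent in 1 genotype. With at most 3 reads over the 4 wild-type libraries, 6 had at least 40 reads over the 4 knockout libraries, up to 436, and 3 showed the reverse. One of the 6, of 638 nt, is listed at 0 in every wild-type library and had 45 reads in the knockout, although knockout 30 min replicate 1 is at 0 too. Whether the knockout cells came from 1 or several clones is not given in the sources used here.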
